A study of Mus musculus with 6 samples.

How the data were processed

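RNA was measured in 6 libraries of mouse hepatocyte organoids, 3 from cultures that received the solvent dimethyl sulfoxide (DMSO) and 3 from cultures that received 20 nM pladienolide B (PlaB). PlaB is a macrolide that binds the SF3b complex of the U2 small nuclear ribonucleoprotein and inhibits pre-mRNA splicing. Per the labels' protocols, hepatocytes were isolated by collagenase perfusion, grown as organoids for 6 days and treated for 6 h, and polyA+ RNA was made into Illumina libraries and sequenced on a NovaSeq instrument. The group of each library was taken from its title, because the treatment tag reads DMSO on all 6 libraries, while the design text names 3 libraries per treatment. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

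The authors deposited 1 table of raw counts per gene, with a column per library and whole numbers that were not normalized. Per the submitters' processing notes, HISAT2, Subread and featureCounts were used with the mm10 mouse genome; their versions and roles, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies therefore cannot be told apart with certainty. The table lists 54532 genes by Ensembl identifier, and 54495 of them were found in the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Gene type, position and number of introns were taken from that annotation. No row lacked a gene, and no column of the table was left out.

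Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 13559 genes. Libraries were scaled by trimmed-mean (TMM) factors, and the quasi-likelihood F test (glmQLFit and glmQLFTest) compared PlaB with DMSO in a model with the group alone, over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM values, with the TMM factors applied, were computed here and are given as mean ± SD over 3 libraries. Log2 fold changes are given with the standard error (SE) of the fit. A count of 0 in a library allows up to 3 counts, which corresponds to between 0.132 and 0.297 CPM. This covers counting error only.

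Before the data were examined, 40 gene lists were written from textbook knowledge, and 1374 of their 1444 members were found by name, 65 by a RefSeq synonym and 5 not at all. Lists were tested with camera (limma 3.58.1) on voom values of the same genes, with the preset inter-gene correlation of 0.01 and adjustment over the 40 lists. For each list, the calls of its members were also adjusted over the list alone. Protein-coding genes were grouped by the number of introns of the transcript with the most exons, and intronless genes were compared with the others by class medians, by camera and by an exact two-sided permutation test over the libraries. The genes named were fixed by a rule: a panel of 10 genes, the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 10 CPM and no overlap between the groups, and for each list the 2 called members with the largest change and at least 5 CPM. Some genes that this rule names are not reported here. Any other gene named was chosen after its values were seen, mostly because 5 or fewer members of a list moved against the rest.

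The alternatives fixed in advance were RLE and upper-quartile factors, library size with no factors, no filter and a stricter filter (mean of at least 1 CPM), DESeq2 1.42.0, limma-voom, the replicate number as a block, mitochondrially encoded genes left out, each library left out in turn, camera with an estimated correlation, and fry. For the intronless class, introns counted in the transcript with the fewest were also fixed in advance. So was leaving histone and mitochondrially encoded genes out of that class. Leaving out both libraries numbered 1, the block with an estimated correlation, and leaving out overlapping protein-coding genes were added after the data were seen. The titles number the replicates 1 to 3 in both groups. Deviations from the group means correlated across genes at 0.592 for the pair numbered 1, at 0.446 for the pair numbered 2 and at 0.198 for the pair numbered 3, so the numbers were taken to pair the libraries. DMSO 3 correlated more with PlaB 2 (0.301) than with PlaB 3. No pair of libraries agreed within sampling noise; the lowest chi-square per degree of freedom was 10.7, between DMSO 2 and DMSO 3.

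The tests were run on simulated counts with the means and library sizes of this comparison and 13559 genes. Of 100 genes changed 2-fold, edgeR recovered 21%, limma-voom 17% and DESeq2 39%, and of 100 genes changed 4-fold they recovered 71%, 68% and 74%. Unchanged genes made up 8.82% of the edgeR calls, 5.5% of those of limma-voom and 24.4% of those of DESeq2. Besides the genes changed 2-fold and 4-fold, only a list of 40 genes was shifted, by 1.5-fold. In the data 64.2% of genes were called. With so few changed genes an adjusted p under 0.05 is harder to reach. These percentages therefore do not carry over to the data. Camera called 0 of 39 unshifted lists and gave an adjusted p of 2.87e-18 for the shifted one, and fry also called 0 of the 39. The simulated genes were drawn independently and the simulated lists at random. The simulation therefore cannot judge list tests where genes vary together. In the real lists the estimated correlation reached 0.90, for hepatocyte secreted proteins.

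Near-identical pseudogenes were sought by aligning annotated pseudogene transcripts to protein-coding transcripts with minimap2 2.31, at 95% identity or more over at least 200 bases. By that search Sf3b4, U2af2, Hnrnpc, Uhrf1, Mki67, Psmd11, Mx2, Hist1h1e, Rps10, Fdps, Gapdh, mt-Atp6 and mt-Nd4l are uncertain, since reads may be shared with a copy. Exons of Ccnd1, Hspa1a, Ppp1r15a, Bid, Cdca8, Rps10, Gnl3, Cxcl10, Shmt1, Gapdh, Fdps, Hist1h1e, Egfl7, Brd2 and both mitochondrial genes overlap exons of another protein-coding gene, and those of Cdkn1a, Cish, Sf3b4, Srsf4, Csrnp1, Bcl3, Hmgcs1, Spp1, Bhlhe40, Snhg15 and Snhg17 overlap a noncoding gene or pseudogene, so their values are uncertain as well.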

Results

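The data are gene counts from polyA+ RNA of mouse hepatocyte organoids, which are 3-dimensional cultures grown from isolated liver parenchymal cells. The 3 DMSO libraries are the background against which the 3 PlaB libraries (20 nM for 6 h) were compared. Total counts per library ran from 14153748 in PlaB 3 to 16822844 in DMSO 3. Haptoglobin (Hp), hemopexin (Hpx), complement C3 and albumin were among the most abundant transcripts in both groups; Hp took 2.02% to 4.68% of the counts of a library. The first principal component of log2 CPM held 79.8% of the variance and separated the treatments, and the second held 12.7% and set both libraries numbered 1 apart from the others. Albumin took 0.601% of the counts in DMSO 1 and 1.06% in PlaB 1, against 3.04% to 5.39% in the other libraries.

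The comparison asked what inhibition of splicing does to gene expression in hepatocytes, a question the series ties to their fate and proliferation. PlaB changed most of the measured transcriptome. On balance, transcripts of p53 targets, immediate early genes, ribosomal proteins, oxidative phosphorylation and intronless genes were higher and those of DNA replication, mitosis and DNA repair lower, though the list tests behind this did not pass with an estimated correlation between genes (adjusted p = 0.755 for each list, p = 0.102 for the intronless class). Of 13559 genes tested, 8703 (64.2%) were called, 4376 higher and 4327 lower in PlaB, and 3130 were higher and 3251 lower by at least 2-fold. In 9471 genes (69.9%) the 3 PlaB libraries all lay above or all below the 3 DMSO libraries, where chance gives 10%.

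The balance of rises and falls depended on the scaling. TMM factors were 1.31 ± 0.128 in DMSO and 0.769 ± 0.103 in PlaB (SD, n = 3), and the 10 most abundant genes took 14.4% ± 3.40 of counts in DMSO and 20.9% ± 3.89 in PlaB (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). With library size alone the median of all genes moved from 0.03 to -0.75 on the log2 scale, and 1901 genes were called higher and 6669 lower, so that 22.2% of calls were rises against 50.3% with TMM. With upper-quartile factors the median was -0.13. Fold changes below are on the TMM scale.

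Among the panel fixed in advance, the p53 targets Mdm2 and Cdkn1a rose and the hepatocyte transcription factor Hnf4a fell. Mdm2, the ubiquitin ligase of p53, stood at 140 ± 34.3 CPM in DMSO and 2466 ± 586 CPM in PlaB (SD, n = 3), a log2 fold change of 4.14 (SE 0.28, adjusted p = 3.04e-05). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, went from 95.4 ± 25.7 to 753 ± 92.7 CPM (log2 2.98, SE 0.23, adjusted p = 4.38e-05). Hnf4a fell from 594 ± 88.2 to 86.0 ± 39.9 CPM (log2 -2.79, SE 0.36, adjusted p = 0.000346). Sf3b1, the SF3b subunit that PlaB contacts, rose from 221 ± 5.69 to 388 ± 6.85 CPM (log2 0.82, SE 0.12, adjusted p = 0.000803), but with library size alone its log2 change was 0.04 and the call was lost (adjusted p = 0.852). Myc rose by 1.63 (SE 0.39, adjusted p = 0.00712); without PlaB 1 it was 0.99, and with library size alone 0.91 (adjusted p = 0.117). The proliferation marker Mki67 fell by 1.13 (SE 0.15, adjusted p = 0.000447).

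The anti-apoptotic Mcl1 passed the test narrowly at a log2 fold change of 0.49 (SE 0.16, adjusted p = 0.0249). That call was lost when any 1 library was left out (adjusted p 0.0538 to 0.0950, and a change of 0.27 without PlaB 1). It was also lost with upper-quartile factors (0.33, adjusted p = 0.116) and without the filter (0.36, adjusted p = 0.151). With library size alone the change was -0.26. With the replicate block the call was kept (0.48, adjusted p = 0.00429). Ccnd1, which encodes cyclin D1, was not called at -0.34 (SE 0.41, adjusted p = 0.486), and was called with the replicate block (adjusted p = 0.0112) and without PlaB 1 (-0.91, adjusted p = 0.0351). Albumin (Alb) was at 17790 ± 11839 CPM in DMSO and 49608 ± 34774 CPM in PlaB, a log2 change of 1.48 that missed the threshold (SE 0.82, adjusted p = 0.149). Alpha-fetoprotein (Afp) was likewise not called at 1.42 (SE 1.45, adjusted p = 0.415). Without PlaB 2 Alb was at 0.86 and Afp at 0.30, and without DMSO 1 Alb was at 0.99 and Afp at 0.83. Each was low in both libraries numbered 1, and with the replicate block both were called (Alb adjusted p = 2.73e-06, Afp adjusted p = 5.62e-06).

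**Figure D1:**
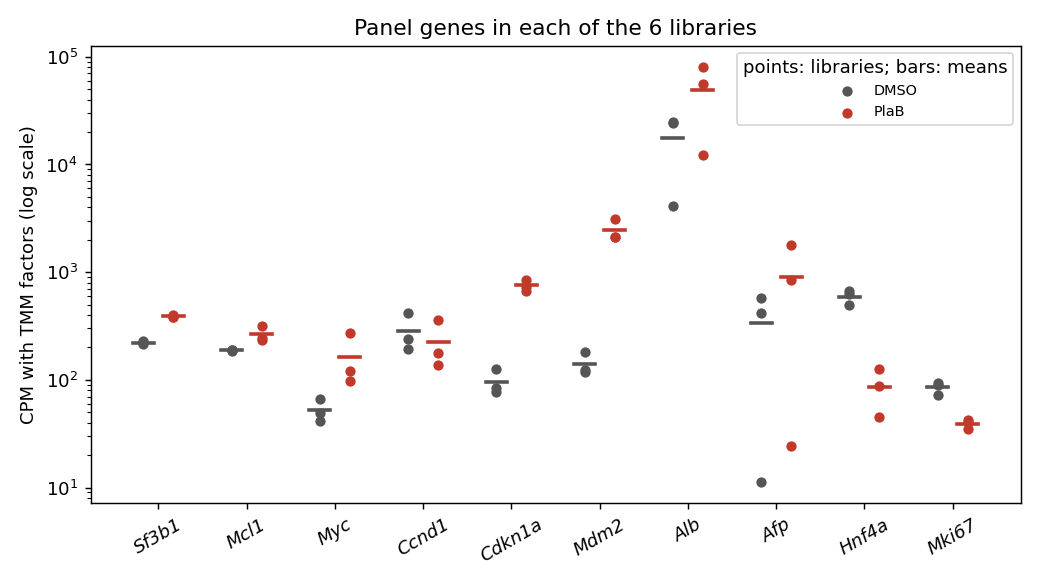
CPM with TMM factors (log axis) of the 10 panel genes in each library, with DMSO in grey and PlaB in red; points are the 3 libraries of a group and bars their means. Mdm2 and Cdkn1a lie higher and Hnf4a and Mki67 lower in all 3 PlaB libraries, while Alb, Afp and Ccnd1 overlap between the groups.

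In the GRCm38 annotation, Mdm2 (ENSMUSG00000020184) spans 117688875 to 117710758 on chromosome 10 and has 11 introns, and Cdkn1a (ENSMUSG00000023067) spans 29090976 to 29100727 on chromosome 17 with up to 2 introns. Hnf4a (ENSMUSG00000017950) lies at 163506808 to 163572910 on chromosome 2 with up to 9 introns, and Sf3b1 (ENSMUSG00000025982) at 54985169 to 55027481 on chromosome 1 with 24 introns.

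Among the large rises were genes with few introns that were close to silent in DMSO. Hic1, a transcriptional repressor at 75164565 to 75169519 on chromosome 11, rose by 6.47 (SE 0.88) from 0.631 ± 0.733 to 58.3 ± 42.8 CPM (SD, n = 3). The intronless p53-inducible gene Rprm (log2 5.66, SE 0.64), the homeobox gene Nkx6-1 (5.66, SE 1.14) and the cytokine signalling inhibitor Cish (5.65, SE 0.35) were also among them. Hist1h1e, a linker histone gene, had a log2 change of 5.47 (SE 1.57, adjusted p = 0.0163) that rested on PlaB 1, with 79.8 CPM there against 3.27 in PlaB 2 and 1.11 in PlaB 3; without PlaB 1 it was 1.72, and the call was lost without DMSO 2 (adjusted p = 0.0573) or DMSO 3 (adjusted p = 0.0597) and in limma-voom (log2 3.61, adjusted p = 0.166).

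Among the largest falls, Synpo, which encodes the actin-associated protein synaptopodin at 60593973 to 60660142 on chromosome 18, fell from 36.8 ± 7.81 to 0.934 ± 0.666 CPM (SD, n = 3; log2 -5.32, SE 0.48, adjusted p = 7.05e-05). S1pr2, a sphingosine 1-phosphate receptor gene at 20962361 to 20976781 on chromosome 9, went from 46.3 ± 3.57 to 2.04 ± 0.367 CPM (log2 -4.49, SE 0.19, adjusted p = 2.00e-05). The other large falls were in Mlph (log2 -4.97, SE 0.58), which encodes melanophilin, in the Golgi traffic gene Arfgap3 (-4.94, SE 0.28), in Tnfaip8l1 (-4.82, SE 0.25) and in Tmem104 (-4.51, SE 0.50). All 6 kept their calls in every alternative fit.

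Of the 40 gene lists, camera called 13 higher, 3 lower and 24 neither way. These calls rest on the preset correlation of 0.01: with an estimated correlation camera called 0 lists, 2 had an unadjusted p under 0.05, and the adjusted p was 0.755 for each of the 16. fry asks whether the genes of a list move one way on balance, without comparing them with other genes. With most genes called, fry cannot show that a list stands out. Of the 16, fry kept 14 and lost the histones (adjusted p = 0.0647) and the secreted proteins (adjusted p = 0.131). It called 9 further lists: other spliceosome proteins, hnRNP, nonsense-mediated decay, heat shock, liver transcription factors, fetal genes, RNA polymerase II, hypoxia and NRF2. With RLE factors no list median changed sign, and with upper-quartile factors 1 did, that of fatty acid oxidation (0.04 to -0.14). With library size alone 16 medians moved from above to below 0, 2 of them in called lists.

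**Figure D2:**
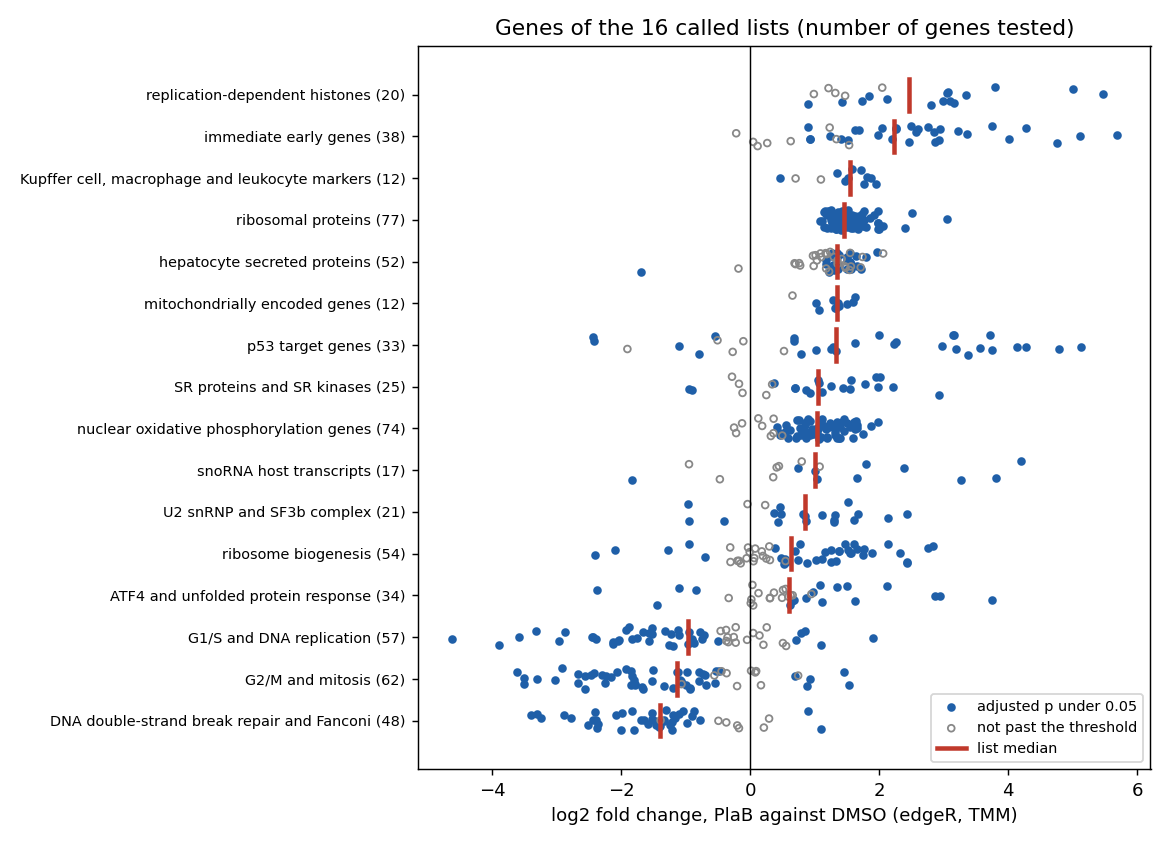
Log2 fold changes (PlaB against DMSO, edgeR with TMM factors) of the members of the 16 called lists, with the number of genes tested in brackets; filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. Medians run from -1.40 for double-strand break repair to 2.47 for replication-dependent histones. With library size alone the medians of ribosome biogenesis (-0.13) and of the ATF4 list (-0.18) lie below 0.

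Transcripts of the splicing machinery rose in its U2 and SR branches. Of 21 genes of the U2 snRNP and SF3b complex, 16 were higher, 3 lower and 2 not called, and the counts were the same when adjusted over the list alone (median log2 0.85; camera adjusted p = 0.00240; adjusted p = 0.755 with an estimated correlation). With library size alone 5 were higher and 4 lower, the median was 0.10, and the list call was lost (adjusted p = 0.0579). Sf3b4 (log2 2.43, SE 0.16) and U2af2 (2.15, SE 0.20), which recognise the branch point and polypyrimidine tract, rose most, and both are uncertain because each has a near-identical pseudogene. Sf3b2 (-0.96), Sf3b6 (-0.95) and U2surp (-0.41) fell. Of 25 SR proteins and SR kinases, 18 rose and 2 fell, also when adjusted over the list alone (median 1.06, and 9 and 6 with library size alone, median 0.27; camera adjusted p = 0.000564; adjusted p = 0.755 with an estimated correlation). Among them were the kinase gene Dyrk1a (2.93, SE 0.15) and Srsf4 (2.22, SE 0.15), while Srsf6 (-0.90) and Srpk1 (-0.95) fell.

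Host transcripts of snoRNAs rose as well, with 9 of 17 higher and 1 lower, Snhg11 at -1.83; the counts were the same when adjusted over the list alone (median 1.01, and 5 and 3 with library size alone, median 0.25; camera adjusted p = 0.0288; adjusted p = 0.755 with an estimated correlation). Snhg17 went from 28.1 ± 8.02 to 515 ± 80.4 CPM (SD, n = 3; log2 4.20, SE 0.27, adjusted p = 2.76e-05), and Snhg15 rose by 3.82 (SE 0.31). The annotation places snoRNA genes on the same strand within both. Without PlaB 1 the list missed the threshold (adjusted p = 0.0580), with its median 0.60 above that of all genes, against 0.98 with all libraries. Of 51 other spliceosome proteins, 25 rose and 10 fell, also when adjusted over the list alone (median 0.54; with library size alone 6 and 18, median -0.21). The list missed the threshold (adjusted p = 0.0546) and passed it without DMSO 1 (adjusted p = 0.0315) or PlaB 2 (adjusted p = 0.0256); Prpf3 (2.43, SE 0.14) and Dhx38 (2.20, SE 0.16) rose most. hnRNP genes gave 16 rises and 6 falls among 27, and 16 and 7 when adjusted over the list alone (median 0.82, adjusted p = 0.0586, and 7 and 10 with library size alone); the list was called with the replicate block (adjusted p = 0.0472) and without DMSO 1 (adjusted p = 0.0397). Its median was 0.54 without PlaB 1. Ptbp2 (2.52, SE 0.24) and Hnrnpc (2.26, SE 0.15) were the largest of these. Nonsense-mediated decay and exon junction genes were mixed, with 8 of 20 higher and 5 lower, Smg9, Smg6, Nbas, Dhx34 and Upf3b (10 and 7 when adjusted over the list alone; adjusted p = 0.337, and 2 and 10 with library size alone, median 0.26 turning to -0.51, and 0.17 without PlaB 3), ranging from Smg8 at 1.70 (SE 0.14) to Smg9 at -2.17 (SE 0.27).

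Among stress-response lists, immediate early genes and p53 targets rose on balance. Of 38 immediate early genes, 30 rose and 0 fell, also when adjusted over the list alone (median log2 2.23, and 21 and 2 with library size alone, median 1.47; camera adjusted p = 2.66e-07; adjusted p = 0.755 with an estimated correlation). The nuclear protein gene Csrnp1 rose from 9.33 ± 1.01 to 323 ± 108 CPM (SD, n = 3; log2 5.11, SE 0.28, adjusted p = 2.28e-05), and Atf3, a stress-induced transcription factor, rose by 4.76 (SE 0.65). Of 33 p53 target genes, 23 were higher and 5 lower, and 23 and 6 when adjusted over the list alone (median 1.34, and 16 and 8 with library size alone, median 0.55; camera adjusted p = 0.000343; adjusted p = 0.755 with an estimated correlation). Plk2, a polo-like kinase, went from 37.0 ± 13.7 to 1299 ± 483 CPM (log2 5.13, SE 0.40), and the stress cytokine Gdf15 rose by 4.78 (SE 0.30). The 5 targets that fell were Dglucy (-2.44), the ribonucleotide reductase subunit Rrm2b (-2.41), the DNA damage sensor Xpc (-1.10), the apoptosome gene Apaf1 (-0.79) and Ccng1 (-0.54).

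The ATF4 and unfolded protein response list had 14 of 34 genes higher and 4 lower, also when adjusted over the list alone (median 0.61; camera adjusted p = 0.0328; adjusted p = 0.755 with an estimated correlation). Sesn2 (3.75, SE 0.18) and the eIF2 phosphatase subunit Ppp1r15a (2.95, SE 0.23) rose most, and the cystine transporter Slc7a11 (-2.37), Atf6 (-1.44), Sel1l (-1.10) and Ern1 (-0.84) fell. The call was lost without DMSO 1 (adjusted p = 0.157; relative median 0.31 against 0.57), without PlaB 2 (adjusted p = 0.0797; 0.36), without the filter (adjusted p = 0.0521) and with library size alone (adjusted p = 0.178; median -0.18). Of 62 replication-dependent histone genes listed, only 20 passed the filter, which can keep a gene for its counts in PlaB alone. Of these 20, 15 were higher and 0 lower, also when adjusted over the list alone (median 2.47, and 5 and 0 with library size alone, median 1.78). Camera gave an adjusted p = 0.00929, and 0.755 with an estimated correlation. The libraries hold polyA+ RNA, so histone transcripts without a polyA tail may be missed. In DMSO Hist1h1e stood at a mean of 0.620 CPM and Hist1h1d at 1.55 CPM. PlaB 1 weighed heavily on the list: the median above all genes was 2.43 with that library and 1.15 without it. Hist1h1d (3.80, SE 1.37, adjusted p = 0.0399) stood at -0.01 without PlaB 1 and was not called without any 1 of the DMSO libraries (adjusted p 0.0880 to 0.111). Its call was also lost in limma-voom (1.97, adjusted p = 0.279) and with library size alone (3.18, adjusted p = 0.0683). Heat shock genes gave 11 rises among 25 and 5 falls, in Chordc1, Dnajb2, Stip1, Hspa4 and Hspd1 (11 and 6 when adjusted over the list alone; adjusted p = 0.374, and 4 and 11 with library size alone, median 0.41 turning to -0.35, and 0.18 without PlaB 1). They were led by Hspa1a (2.72, SE 0.50) and Dnajb5 (2.28, SE 0.17). Regulators of the BCL2 family were split 6 higher and 6 lower of 17, also when adjusted over the list alone (adjusted p = 0.844, and 2 and 9 with library size alone). The p53-inducible Bbc3 rose by 3.57 (SE 0.33) and Bid fell by 4.19 (SE 0.39).

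Genes of the cell cycle and of DNA repair fell together. Of 57 G1/S and DNA replication genes, 37 were lower and 5 higher (median log2 -0.96; camera adjusted p = 7.61e-05; adjusted p = 0.755 with an estimated correlation). Of 62 G2/M and mitosis genes, 47 were lower and 5 higher (median -1.13; camera adjusted p = 5.25e-07; adjusted p = 0.755 with an estimated correlation). Of 48 double-strand break repair and Fanconi genes, 39 were lower and 2 higher (median -1.40; camera adjusted p = 4.20e-07; adjusted p = 0.755 with an estimated correlation). All 3 pairs of counts were the same when adjusted over the list alone, and the lists kept their direction with every scaling. The replication initiator Mcm10 fell from 11.2 ± 0.773 to 0.741 ± 0.221 CPM (SD, n = 3; log2 -3.90, SE 0.30, adjusted p = 4.38e-05), and the spindle checkpoint kinase gene Bub1b from 16.6 ± 0.385 to 1.35 ± 0.291 CPM (-3.61, SE 0.24, adjusted p = 2.81e-05). Uhrf1 (-3.33, SE 0.21), Cdca8 (-3.50, SE 0.32) and Brca1 (-3.30, SE 0.26) fell to a similar degree. Against this trend, E2f3 (1.90), Cdc25a (1.11), Cdc6 (0.84), Mcm3 (0.79) and Ccnd3 (0.72) rose in the replication list, Wee1 (1.53), Incenp (1.45), Foxm1 (0.94), Bub3 (0.89) and Sgo2a (0.70) in the mitosis list, and Fancf (1.10) and Atrip (0.90) in the repair list. On library size alone Ccnd3 was at -0.05 and Sgo2a at -0.07. Fold changes also fell with the number of introns, to a median of -0.50 in protein-coding genes with over 10. Brca1 and Bub1b have up to 22 introns, Mcm10 19, Uhrf1 up to 16 and Cdca8 up to 9. Only ribosomal protein genes were compared with genes matched on introns. How much gene structure adds to the other lists and to the name stems was not tested.

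Ribosomal protein genes moved as one block. All 77 were higher and called, also when adjusted over the list alone (median log2 1.46; camera adjusted p = 9.41e-21; adjusted p = 0.755 with an estimated correlation), and with library size alone 54 were higher and 0 lower (median 0.68). Their share of counts was 3.09% ± 0.528 in DMSO and 4.82% ± 0.874 in PlaB (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Rps10 (3.05, SE 0.30) rose most, and its value is uncertain because of overlapping genes and pseudogenes. In ribosome biogenesis 32 of 54 genes were higher and 5 lower, and 33 and 5 when adjusted over the list alone (median 0.63; camera adjusted p = 0.000400; adjusted p = 0.755 with an estimated correlation). Scaled by library size alone, 16 were higher and 17 lower and the median was -0.13. Nucleostemin (Gnl3, 2.84, SE 0.23) and the intronless Rrs1 (2.75, SE 0.19) rose, while Ltv1 (-2.40), Wdr12 (-2.09), Wdr75 (-1.27), Polr1a (-0.95) and Nop14 (-0.69) fell.

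Both arms of oxidative phosphorylation were higher. Of 74 nuclear genes, 65 rose and 0 fell (median log2 1.03; camera adjusted p = 5.80e-11; adjusted p = 0.755 with an estimated correlation), led by Atp5k (1.99, SE 0.18) and Ndufa1 (1.88, SE 0.18). Of 12 mitochondrially encoded genes, 11 rose and 0 fell (median 1.35; camera adjusted p = 0.00144; adjusted p = 0.755 with an estimated correlation), with mt-Atp6 at 1.62 (SE 0.24) and mt-Nd4l at 1.60 (SE 0.42), the latter 0.96 without PlaB 2 and not called with library size alone (adjusted p = 0.105). Both lists gave the same counts when adjusted over the list alone. Scaled by library size alone, 26 nuclear genes were higher and 7 lower (median 0.25), and 2 mitochondrial genes were higher (median 0.59). Mitochondrial transcripts took 3.36% ± 0.602 of counts in DMSO and 4.86% ± 0.995 in PlaB (SD, n = 3; exact two-sided permutation p = 0.1).

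Among the lists of hepatocyte function, secreted plasma proteins were higher and the rest were not called. Member counts are from the fit without the replicate block, so a gene not called there may be called with it. Alb and Afp were such genes, as was the transcription factor gene Creb3l3 (log2 -0.98, adjusted p = 0.114, and 5.05e-05 with the block). Of 52 genes for secreted proteins, 23 rose, 1 fell (Apoc2, -1.68) and 28 were not called, with 21 and 1 when adjusted over the list alone (median log2 1.35, and 8 and 1 with library size alone, median 0.55; camera adjusted p = 0.000985; adjusted p = 0.755 with an estimated correlation). Serpina1e (1.97, SE 0.39) and Apoc1 (1.80, SE 0.42) rose most. The list moved with the libraries that stood apart: it took 7.90% of counts in DMSO 1 and 11.3% in PlaB 1, against 12.7% ± 4.17 over all DMSO and 18.5% ± 6.47 over all PlaB libraries (SD, n = 3; exact two-sided permutation p = 0.3, which ignores the pairing). Within the pairs it was higher in PlaB each time (15.4% to 23.8% for those numbered 2 and 14.8% to 20.4% for those numbered 3). Liver-enriched transcription factors were split, with 12 of 26 higher and 8 lower, and 13 and 8 when adjusted over the list alone (adjusted p = 0.368). The balance turned with library size alone, to 5 higher and 11 lower (median 0.43 to -0.34). Besides Hnf4a, the repressor gene Zhx2 fell by 3.22 (SE 0.35).

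The lists of liver metabolism were not called, and their counts of rises and falls depended on the scaling. These counts too are from the fit without the replicate block. With the block none of these lists was called by camera (adjusted p 0.0987 to 0.615). In the cytochrome P450 and xenobiotic list 3 of 35 genes rose (Gstp1, Ugt2b34 and Ephx1) and 4 fell, and 1 and 3 when adjusted over the list alone (adjusted p = 0.839, and 0 and 7 with library size alone, median 0.52 turning to -0.29, with Ephx1 at -0.10). Without 1 library that median ran from -0.04 (PlaB 2) through 0.29 (DMSO 1) to 0.92 (PlaB 1) and 0.97 (DMSO 2). The falls were in Fmo5 (-1.50, SE 0.39), the P450 reductase gene Por (-1.37, SE 0.20), Sult1a1 and Aox1. Amino acid and urea cycle genes gave 2 rises and 4 falls among 35, and 1 and 4 when adjusted over the list alone (adjusted p = 0.368, and 0 and 15 with library size alone), with Ahcy and Got1 higher (-0.29 and -0.33 with library size alone) and Shmt1 (-2.00, SE 0.25), Prodh (-1.50, SE 0.29), Slc25a13 and Gldc lower. Glucose and glycogen genes gave 10 rises among 29 and 4 falls, among them the glucose transporter gene Slc2a2, Pfkfb1 and Hk1, also when adjusted over the list alone (adjusted p = 0.337, and 2 and 9 with library size alone, median 0.46 turning to -0.33, and 0.30 without PlaB 2). Gapdh, a usual reference gene, rose by 3.10 (SE 0.18), but it has 87 near-identical pseudogenes and its value is uncertain. Hk2 rose by 1.41 (SE 0.31, and 0.92 without PlaB 1). With library size alone Hk2 was at 0.67 (adjusted p = 0.169). Cholesterol and fatty acid synthesis gave 9 rises among 35 and 3 falls, in Insig2, Mvk and Acly, and 8 and 2 when adjusted over the list alone (adjusted p = 0.352, and 6 and 13 with library size alone, median 0.32 turning to -0.47, and 0.10 without DMSO 1, 0.06 without PlaB 2 and 0.51 without DMSO 2). Among its members were Hmgcs1 at 2.21 (SE 0.40) and Fdps at 2.97 (SE 0.29). Fatty acid oxidation and peroxisome genes gave 9 rises and 11 falls among 43, also when adjusted over the list alone (adjusted p = 0.689, and 2 and 24 with library size alone, median -0.78). There Pdk4 rose by 2.93 (SE 0.35) and the carnitine palmitoyltransferase gene Cpt1a fell by 2.40 (SE 0.20), and the list's median (0.04) and mean (-0.10) differed in sign. That median ran from -0.22 without PlaB 2 to 0.12 without DMSO 2. Bile acid genes gave 1 rise (Klb) and 3 falls among 18, and 1 and 2 when adjusted over the list alone (adjusted p = 0.368, and 1 and 10 with library size alone), with falls of the bile acid receptor gene Nr1h4 (-1.83, SE 0.25), Nr0b2 and Abcc4 (-1.19, SE 0.14).

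Several markers of other liver cells were higher, and most of these calls depended on the scaling. Only part of each list passed the filter: 12 of 28 macrophage and leukocyte markers, 15 of 20 cholangiocyte, 8 of 26 stellate and 5 of 24 endothelial markers. Of 12 tested markers of Kupffer cells, macrophages and leukocytes, 10 rose and 0 fell, also when adjusted over the list alone (median log2 1.55; camera adjusted p = 0.0365; adjusted p = 0.755 with an estimated correlation), with Cd74 at 134 ± 42.5 CPM in DMSO and 471 ± 139 CPM in PlaB (SD, n = 3; 1.81, SE 0.31) and Lyz2 at 1.87 (SE 0.59). The list call was lost without DMSO 2 (adjusted p = 0.0592) and without PlaB 1 (adjusted p = 0.0888), and with library size alone 1 member was called higher. Cholangiocyte markers gave 4 rises and 1 fall (Bicc1) among 15 (adjusted p = 0.229), the rises being Spp1 (1.76, SE 0.52), Epcam (1.42, SE 0.35), Sox9 and Slc4a2 (-0.18 with library size alone). Scaling by library size gave 0 rises and 4 falls, and without PlaB 2 the list was called (adjusted p = 0.0435), with its median 1.48 above that of all genes against 0.84 with all libraries. Stellate and fibroblast markers gave 3 rises among 8 (adjusted p = 0.229), in Dcn (1.59, SE 0.30), Ecm1 (1.57, SE 0.23) and Sparc. These counts were the same when adjusted over the list alone. Endothelial markers gave 2 rises among 5, and 1 when adjusted over the list alone (adjusted p = 0.763), with Egfl7 at 1.12 (SE 0.26) and Bmp2 as the other (0 rises and 2 falls with library size alone); the median of these 5 genes was -0.29 and their mean 0.33. The median ran from -0.98 without PlaB 2 to -0.03 without DMSO 2, with each library but DMSO 3 moving it over 1.5 times. Fetal liver and progenitor genes gave 9 rises and 2 falls among 22, also when adjusted over the list alone (median 1.07, adjusted p = 0.229), and were called with the replicate block (adjusted p = 0.0213) and without both libraries numbered 1 (adjusted p = 0.0458), while library size alone gave 1 rise and 4 falls; Dlk1 was at 2.48 (SE 0.72) and lost its call without DMSO 2 (adjusted p = 0.0503), PlaB 2 (0.0637) or PlaB 3 (0.0516), and Igf2bp3 and Krt23 were the falls. Scaled by library size alone, Spp1, Epcam, Dcn, Egfl7 and Lyz2 were no longer called. Lyz2 also lost its call without DMSO 2 (adjusted p = 0.0614), DMSO 3 (0.0849), PlaB 1 (0.0707) or PlaB 3 (0.0593), and Spp1 without DMSO 2 (0.0527) or DMSO 3 (0.0682).

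The remaining signalling and housekeeping lists were not called, and library size alone gave each fewer rises. Of 39 interferon-stimulated genes, 19 rose and 7 fell, also when adjusted over the list alone (median log2 0.66, adjusted p = 0.118; with library size alone 9 and 11, median -0.12). That list was called without PlaB 2 (adjusted p = 0.0130, its median 0.77 above that of all genes); Mx2 (5.44, SE 0.38) and Rsad2 (5.13, SE 0.51) were among the steepest rises of the whole set of lists. NF-kB and inflammatory genes gave 18 rises and 8 falls among 31 (adjusted p = 0.241, and 7 and 9 with library size alone), from the chemokine Cxcl10 at 3.60 (SE 0.62) to the NF-kB cofactor gene Bcl3 at -4.02 (SE 0.35). YAP/TEAD targets gave 8 rises among 22 and 4 falls, in Tead4, Asap1, Wwc1 and Tead1 (adjusted p = 0.687, and 7 and 7 with library size alone, median 0.22 turning to -0.56). That median was near 0 without PlaB 1 or PlaB 3, 0.10 without DMSO 2, 0.12 without DMSO 3 and 0.40 without DMSO 1. Among its members were Amotl2 at 4.55 (SE 0.47) and Cyr61 at 3.76 (SE 0.74; 2.29 without PlaB 1). TGF-beta and epithelial-mesenchymal genes gave 12 rises among 23 and 5 falls, in Id3, Smad6, Id1, Cdh2 and Itgav (adjusted p = 0.225, and 2 and 5 with library size alone), with Ski at 2.46 (SE 0.21). Genes of RNA polymerase II transcription gave 18 rises and 13 falls among 47 (adjusted p = 0.337, and 11 and 24 with library size alone, median 0.25 turning to -0.52, and 0.09 without PlaB 1). The largest subunit gene Polr2a was at -2.37 (SE 0.23, adjusted p = 9.79e-05), while Brd2 rose by 2.93 (SE 0.23). Proteasome genes gave 11 rises and 8 falls among 32 (adjusted p = 0.689, and 0 and 20 with library size alone, median 0.19 turning to -0.60, and 0.09 without PlaB 2 and 0.12 without PlaB 3), with Psmd11 (-1.41, SE 0.12) and Psmd12 (-1.21, SE 0.15) lower. NRF2 targets gave 11 rises among 25 and 3 falls, in Slc7a11, Abcc4 and Gsr (adjusted p = 0.121, and 3 and 11 with library size alone, median 0.52 turning to -0.25), with Osgin1 at 2.57 (SE 0.19). These counts were the same when adjusted over the list alone. Hypoxia genes gave 11 rises and 6 falls among 22, and 11 and 7 when adjusted over the list alone (adjusted p = 0.341, and 4 and 8 with library size alone, median 0.67 turning to -0.10), with Ddit4 at 1.69 (SE 0.33; not called with library size alone, adjusted p = 0.0695) and Bhlhe40 at 1.59 (SE 0.27).

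Because PlaB inhibits splicing, genes were also compared by their number of introns. Intronless protein-coding genes rose, and the response fell step by step as introns became more numerous. Of 256 intronless genes, 181 (70.7%) were higher and 9 (3.52%) lower, with a median log2 fold change of 1.51. Medians were 0.71 in 1060 genes with 1 to 2 introns, 0.29 in 2647 with 3 to 5, -0.12 in 3390 with 6 to 10 and -0.50 in 4590 with over 10, and of the last class 913 (19.9%) were higher and 2089 (45.5%) lower. With library size alone the order was the same but the medians were 0.75, -0.05, -0.49, -0.90 and -1.27, so the direction of the classes with 1 to 5 introns depends on the scaling.

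The median of the intronless class exceeded that of the 11687 genes with introns (-0.12) by 1.63 on the log2 scale. Camera gave p = 4.99e-14 for the intronless class with the preset correlation, and p = 0.102 with an estimated correlation. Per library, the median log2 CPM of intronless genes minus that of genes with introns was -1.89 ± 0.110 in DMSO and -0.23 ± 0.265 in PlaB (SD, n = 3), with all PlaB libraries above all DMSO libraries (exact two-sided permutation p = 0.1, the smallest possible). The counts are per gene and do not separate spliced from unspliced transcripts.

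**Figure D3:**
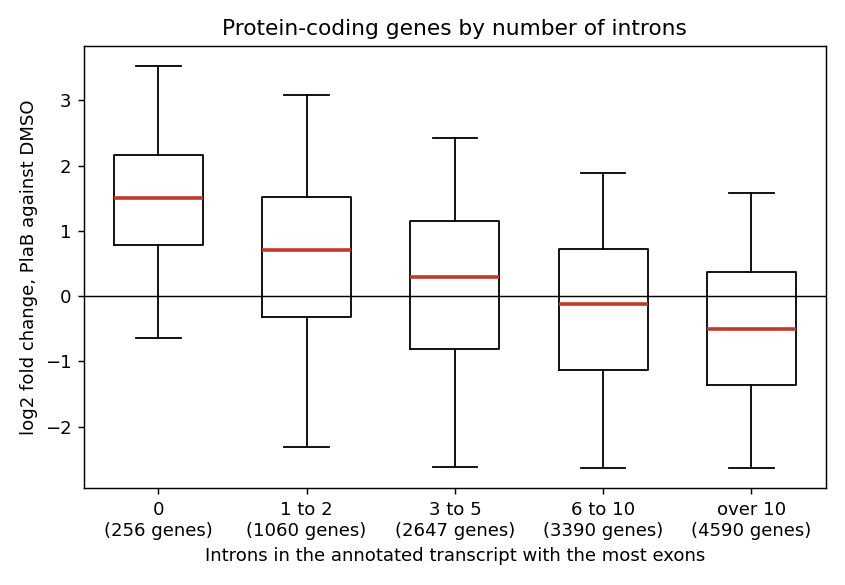
Log2 fold changes (PlaB against DMSO) of protein-coding genes by the number of introns in the annotated transcript with the most exons; red lines are medians, boxes span the quartiles and whiskers the 5th to 95th percentiles. The median falls from 1.51 in intronless genes to -0.50 in genes with over 10 introns, and with library size alone from 0.75 to -1.27.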

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

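The added tests without both libraries numbered 1, with the block and an estimated correlation together, and without overlapping protein-coding genes were chosen after the data were seen. With library size alone 1901 genes were called higher and 6669 lower, against 4376 and 4327, and at least 2-fold 1351 higher and 5575 lower, against 3130 and 3251. That alternative omits the factors by which TMM raised PlaB values relative to DMSO. Of the 8703 calls, 6228 were kept with it in the same direction and 2 were called the other way. No-filter, stricter-filter, RLE, upper-quartile, DESeq2, limma-voom and mitochondria-free fits called between 8315 and 9435 genes, and leaving out each library in turn called between 7660 and 9087. Without both libraries numbered 1, 9750 genes were called and 8397 of 8693 tested calls kept their direction. With the replicate block 9912 genes were called, 5031 higher and 4881 lower, and 8668 of the 8703 calls were kept; the difference between intronless genes and the rest was 1.62. Over all alternatives that difference ran from 1.44 (introns counted in the transcript with the fewest) to 1.79 (without PlaB 2), and it was 1.65 without overlapping genes.

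With an estimated correlation 0 lists were called higher and 0 lower, and likewise 0 and 0 with the replicate block and an estimated correlation together (adjusted p = 0.614 for the called lists); fry called 20 higher. The replicate block kept the 16 called lists, and besides the hnRNP and fetal lists, Ccnd1, Alb and Afp it changed no other call of a list, a panel gene or a gene named by the rule; Arntl, chosen later, is given below. Relative to all genes, the median of the fatty acid oxidation list was 0.01 and turned to -0.02 with RLE factors (-0.0157), -0.0081 with upper-quartile factors, -0.0389 with library size, -0.0891 without the filter and -0.0491 with the replicate block, with or without an estimated correlation. The range over fits without 1 library was -0.19 to 0.19 for that list, -0.45 to 0.33 for amino acid and urea cycle metabolism (0.0048 without both libraries numbered 1), -0.46 to 0.10 for the BCL2 family and -0.0057 to 0.99 for cytochrome P450 and xenobiotic metabolism. None of these lists was called in any fit. Mcl1 turned to -0.26 with library size, Ccnd1 ranged from -0.911 to 0.0297 and Hist1h1d from -0.009 to 4.36 without 1 library. The cause of these reversals was not tested. Of the other values for named genes, 1512 kept their direction and side of the threshold, 44 lost the threshold and 7 passed it; for lists these numbers were 605, 42 and 17. In simulated counts, where few genes were changed, 21% of 2-fold changes were recovered, and that share does not carry over to the data. A gene that was not called may still have changed.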

Other observations

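The transcription factors, clock genes and name stems in this part, the test of genes with 1 to 2 against over 10 introns and the test of ribosomal protein genes with library size were chosen after the values were seen. Liver-enriched transcription factors moved in both directions. Besides Hnf4a, the nuclear receptor genes Ppara (log2 -2.71), Nr1i2 (-2.53), Nr1h3 (-1.94) and Nr1h4 (-1.83) fell, while Gata6 (2.41), Onecut1 (2.28), Foxa2 (2.23), Cebpa (1.63) and Gata4 (1.48) rose. Genes of the circadian clock also moved in opposite directions: of 16 tested, 8 rose, 6 fell and 2, Arntl and Tef, were not called, Arntl being called with the replicate block (adjusted p = 0.0126). The D-box factor gene Dbp went from 4.77 ± 0.404 to 157 ± 19.1 CPM (SD, n = 3; log2 5.03, SE 0.17, adjusted p = 2.00e-05) and the repressor gene Nr1d1 rose by 5.38 (SE 0.27), Per1 by 3.72 (SE 0.22) and Ciart by 2.84 (SE 0.26). Per3 (-2.84, SE 0.23), Hlf (-2.35, SE 0.25) and Cry1 (-1.86, SE 0.21) fell. The genes named with values kept these signs with RLE, upper-quartile and library size scaling.

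Protein-coding genes were also grouped by the stem of their symbol, which gave 105 stems of at least 12 genes and 210 Fisher's exact tests (one-sided), adjusted together. Calls were enriched among rises for 8 stems and among falls for 4. Zinc-finger genes with the stem Zfp had 153 rises and 78 falls among 325 (adjusted p = 1.09e-09; median log2 0.58, but -0.20 with library size alone). The Krueppel-like factors (Klf) had 10 rises and 1 fall (Klf15) among 13 (adjusted p = 0.0154; median 1.80) and the dual-specificity phosphatases (Dusp) 13 and 3 (Dusp12, Dusp19 and Dusp22) among 19 (adjusted p = 0.0154; median 1.24). Kinesin genes (Kif) had 2 rises (Kif18b, and Kif1c, which turned to -0.15 with library size alone) and 21 falls among 30 (adjusted p = 0.00272; median -1.41) and nucleoporin genes (Nup) 6 and 14 among 21 (adjusted p = 0.0466; median -0.71). The Klf, Dusp, Kif and Nup medians kept their sign with library size alone. The stems Hist, Rpl, Rps, Cox and Ndufa, enriched among rises, and Ap and Phf, enriched among falls, complete the 12. Members of a family share sequence and history, so the tests overstate the evidence. Klf and Dusp genes are in part immediate early genes and Kif genes in part mitotic.

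Of 932 noncoding genes tested 528 were higher and 137 lower (median log2 1.64), beside 3543 higher (29.7%) and 4122 lower of 11943 protein-coding genes; the difference of these shares was not tested. All 70 snoRNA genes tested were higher (median log2 4.62), as were 138 of 188 genes of the TEC type, which mark loci whose transcript awaits experimental support, and 165 of 262 antisense genes (medians 2.82 and 2.21). These 3 medians were the same with the genes that had no count in DMSO placed at their bound of 3 counts over the group. Only 2 snoRNA, 9 TEC and 8 antisense genes had no count in DMSO. That check therefore says little about genes near silent there. The filter keeps a gene that is high enough in 3 libraries. A gene near silent in DMSO was thus tested only if it was high in PlaB, which favours rises among such genes. Other types moved less: lincRNA genes had 73 rises and 54 falls among 211 (median 0.41, but -0.35 with library size alone). Processed transcripts had 52 and 29 among 134 (median 0.59). Strand was not stated, so the antisense values are uncertain. Of the 70 snoRNA genes, 64 overlap a tested protein-coding gene on the same strand (median 4.51, and 1.19 for the overlapped genes). The libraries hold polyA+ RNA, so snoRNAs without a polyA tail may be missed. Reads of host transcripts were not separated from those of snoRNAs. Whether mature snoRNAs rose was therefore not tested.

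Whether the noncoding genes lie in the reach of other genes was weighed against scaling. Of the 512 that rose at least 2-fold 92.97% and of the 420 others 77.86% lay inside or within 10 kb of a tested protein-coding gene (odds ratio 3.76, 95% interval 2.46 to 5.83, two-sided Fisher's exact p = 3.49e-11). Those overlapping a gene on the same strand had a median of 3.73 (214 genes) and those opposite a gene 2.14 (410), while the 129 with no such neighbour had 0.16 (95% bootstrap interval -0.37 to 0.59) and the 50 within 10 kb downstream had -0.01. With library size the median of all 932 was 0.88 (0.57 to 1.11). It was 2.97 for genes overlapping another on the same strand and 1.40 for those opposite a gene, which argues against scaling alone for these 2 classes. The other classes lay below 0 with library size. Their medians were -0.58 with no tested protein-coding gene within 10 kb, -0.79 downstream and -0.24 in other arrangements. A candidate explanation, as a hypothesis, is that reads of retained introns or unspliced transcripts of the surrounding genes were counted to noncoding genes inside them, and transcription of these genes themselves was not tested. Fisher's test and the bootstrap intervals, here and below, take genes as independent with the 6 libraries fixed. They do not measure the spread between libraries.

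The fall of the response with intron number was weighed against other properties of the genes. Of 1316 genes with 0 to 2 introns, 921 had matches with over 10 introns on transcript length, GC content and expression. Their median exceeded that of the averages over up to 5 matches each by 1.42 (95% bootstrap interval 1.30 to 1.57). Before matching, the difference over all 1316 was 1.39. The matched value argues against these properties as the whole cause. The fall was not a matter of intronless genes alone, since genes with 1 to 2 introns exceeded those with over 10 by 1.21 (1.10 to 1.32). Genes with many introns may therefore be the most sensitive to the inhibitor under this treatment, as a hypothesis found and tested on the same data. Different stability of the transcripts and the way unspliced reads were counted were not tested. The intervals resample genes only. Over the libraries, the exact permutation test of intronless genes against the rest gave p = 0.1, the smallest possible.

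The rise of ribosomal protein genes was set against pseudogenes, scaling and gene structure. The 7 genes without a near-identical pseudogene had a median of 1.59 (95% bootstrap interval 1.37 to 1.68; 1.44 in the other 70), and the list median with library size alone was 0.68 (0.63 to 0.76), so neither shared reads nor TMM scaling accounts for the whole rise. For each gene, up to 5 genes outside the list, matched on transcript length, introns, GC content and expression, were averaged. A gene could serve as a match more than once, and which genes served was not examined. These averages had a median of 1.14, and the list exceeded it by 0.31 (0.22 to 0.44). Most of the rise may thus be shared with genes alike in all of these properties, and a smaller part specific to ribosomal proteins cannot be told apart from incomplete matching, since 0.31 lies between the bounds of 0.3 and 0.6 set before the test.

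Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real split, namely itself, both for all calls (8703) and for those of at least 2-fold (6381); the highest of the others was 0 in edgeR and in limma-voom, with 4 to 344 genes at an unadjusted p under 0.05 in edgeR. With 10 splits the share cannot fall below 0.1, so they are too few to judge chance. The 3 other splits that part all 3 pairs put DMSO and PlaB libraries on both sides and called 0 genes.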
